A study of Mus musculus with 68 samples.

How the data were processed

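RNA from the uterus of ovariectomized mice was measured on 68 arrays, 1 per sample, in 25 groups of 2 or 3 arrays. The series describes 3 replicates per treatment. In groups of 2 arrays it says that the authors left out an outlier by principal component analysis. The spread between samples may therefore be understated in the 7 groups that hold 2 arrays. Replicates are taken as labelled, so a p value measures the spread between samples. The arrays come from 3 mouse sets, each with its own vehicle, oestradiol (E2) and insulin-like growth factor 1 (IGF1) arrays. These are C57Bl6 wild types, Ex3aERKO mice (with a null allele of Esr1, the gene of oestrogen receptor alpha, ERα) with their wild-type littermates, and ERaUtcKO mice (a floxed Esr1 allele removed by Cre under the progesterone receptor promoter) with theirs. Tissue was taken 2 h or 24 h after treatment, and vehicle only at 24 h. For IGF1 the labels name both an injection and an implanted pump, not which mice had which, so the route is unknown.

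The deposited table holds log2 intensities for 72688 probe sets, summarised and normalized by the authors. The normalization method is not given in the sources used here. Values end at 19.9315, and 16 tested genes came within 0.01 of that ceiling on at least 1 array. The median of the 72688 values ran from 6.43 to 6.60 on the C57 arrays, from 5.82 to 6.15 on the Ex3aERKO arrays and from 6.26 to 6.62 on the ERaUtcKO arrays. Every comparison was therefore made within a set or with the set as a model term, without further scaling. Differences are on the deposited log2 scale. Arrays give no depth, so their number limits the precision. The median of the antigenomic control probe sets, which match no mouse sequence, was 4.31, 3.46 and 3.65 in the 3 sets.

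Of the probe sets, 32750 were in the annotation and 30604 carried 1 gene symbol. The 2146 with several symbols and the 39938 outside the annotation (6732 of the table's probe sets are controls) were left out. Symbols were updated through the Entrez identifier for 22818 probe sets and by symbol for 7476, while 310 kept the file symbol. This changed 827 symbols. Where a gene had more than 1 probe set (355 genes), the one with the highest mean over the 68 arrays was kept, which left 30142 genes, 19046 of them protein coding. No filter on level was applied.

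Linear models were fitted with limma 3.58.1 in R 4.3.3, with moderated variances and Benjamini-Hochberg adjustment over the 30142 genes. A gene is called changed at an adjusted p under 0.05, two-sided. Wild-type responses came from a model of the 42 wild-type arrays with treatment and mouse set as terms (35 residual degrees of freedom). They were also computed in each set alone. Responses of the knockout lines came from the 25 arrays of the Ex3aERKO experiment and the 29 of the ERaUtcKO experiment, each with 1 mean per group (15 and 19 residual degrees of freedom). The interaction tests compare the response to a hormone in a knockout line with that in its wild-type littermates. In all, 24 comparisons were tested.

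Gene lists were 33, namely 19 of pathways or hormone responses and 14 of cell types, written from textbook knowledge. They were tested against all other genes with camera of limma at a preset correlation between genes of 0.01 and again at an estimated one, adjusted over the 33 lists in each comparison. Signatures were the genes called at 2-fold or more in the C57 wild types alone, and their signed response in each knockout line and its littermates was compared with fry of limma, adjusted over the 8 signature tests. Genes are named by a rule. For a wild-type response these are the 8 largest rises and 8 largest falls among called genes with the same sign in each of the 3 sets, and for any other comparison the 5 largest of each. Predicted and RNA genes are passed over. In every comparison 15 genes of the ERα and IGF1 pathways are added, of which Insr and Ccnd1 were not measured by a probe set of their own. For each list described, up to 4 members are added, the 2 largest rises and 2 largest falls among those called or, where none is called, those that moved furthest.

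Groups, comparisons, lists, the threshold, the naming rule and the alternatives were set before the data were examined. The exceptions are the centring of each array on its median, the list of liver transcripts, the choice of which lists (108 of the 271 list tests that passed) and which interaction genes to describe, and the tests named in the closing section as chosen later. The models were tested on simulated data with the spread of these arrays. In simulations without any change, 0 of 30142 genes were called by limma. With changes of log2 0.5, 1 and 2 put in, the model for E2 at 2 h in wild types recovered 79.1%, 98.5% and 100% of them. The interaction test for IGF1 at 2 h recovered 2.99%, 43.3% and 90.9% in the Ex3aERKO experiment and 22.4%, 68.7% and 98.5% in the ERaUtcKO experiment. For IGF1 at 24 h it recovered 8.96%, 56.7% and 92.4%, and 20.9%, 73.1% and 97.0%. The alternatives tried were quantile normalization, a filter on level, the mean of all probe sets of a gene, a replicate block, only the arrays of the groups compared, each mouse set alone, a further limit of 2-fold, signatures at any fold, an estimated correlation, leaving out each array in turn and, added later, centring each array on the median of its tested genes. Replicate numbers do not pair arrays across groups, so the block is only 1 of these alternatives.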

Results

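The 68 arrays measured the uterus of ovariectomized female mice after vehicle, E2 or IGF1. There were 14 arrays of C57Bl6 wild types, 14 of Ex3aERKO wild-type littermates and 11 of Ex3aERKO mice. A further 14 arrays came from ERaUtcKO wild-type littermates and 15 from ERaUtcKO mice. Wild types gave 8 vehicle arrays and 9 each for E2 at 2 h and 24 h. For IGF1 they gave 7 at 2 h and 9 at 24 h. The title of the series asks what part ERα plays in the uterine response to IGF1. Vehicle tissue was taken at 24 h alone, so each 2 h comparison also spans a difference in time since treatment. Values below are differences in log2 intensity with their standard error (SE), and "rose" and "fell" stand for an adjusted p under 0.05 in limma.

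Esr1, which encodes ERα, was lower in both knockout lines. Under vehicle it fell by 2.39 ± 0.19 (SE, adjusted p = 1.8e-06, 2 and 2 arrays) in Ex3aERKO and by 1.21 ± 0.11 (adjusted p = 3.66e-07, 3 and 3 arrays) in ERaUtcKO. Over the other treatments its difference ran from -1.81 to -2.14 in Ex3aERKO and from -1.23 to -1.69 in ERaUtcKO. In every treatment each knockout array lay below each littermate array. Esr2, the gene of oestrogen receptor beta, had a mean of 4.67 in the Ex3aERKO experiment and 4.80 in the ERaUtcKO experiment, and its vehicle differences were -0.02 (adjusted p = 0.987) and 0.04 (adjusted p = 0.847).

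In wild-type uterus, E2 at 2 h raised Greb1, a direct target of ERα, by 4.88 ± 0.11 (adjusted p = 1.63e-31, 9 E2 and 8 vehicle arrays). The largest rises were those of Klk1, a kallikrein protease, by 8.84 ± 0.29, of Pgf, a growth factor of the VEGF family, by 6.55 ± 0.11 and of Mad2l1, a spindle checkpoint gene, by 6.54 ± 0.16. Rgs2, a regulator of G protein signalling, fell by 4.50 ± 0.17 and Rspo3, an enhancer of WNT signalling, by 4.45 ± 0.17. Within the IGF1 pathway, Igf1 itself rose by 2.31 ± 0.13 while Irs2, an adaptor of the insulin and IGF1 receptors, fell by 2.29 ± 0.19 and Igf1r fell by 0.46 ± 0.10. Pgr, the progesterone receptor gene, rose by 2.10 ± 0.12, and Esr1 fell by 0.65 ± 0.09.

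Of 20 early E2-responsive uterine genes, 19 rose 2 h after E2, among them Gadd45g by 6.53 ± 0.22, and Sox4 fell by 3.47 ± 0.10. The counts adjusted over the list alone were also 19 and 1, and the list stood above other genes (median 3.43, adjusted p = 2.44e-20, and adjusted p = 7.37e-06 with an estimated correlation). Immediate-early transcription factor genes rose in 20 of 21 cases (20 adjusted over the list alone), led by Nr4a1 at 5.12 ± 0.44. Their median was 1.92 (adjusted p = 2.93e-18, and adjusted p = 0.0198 with an estimated correlation). All 10 heat-shock genes rose (10 adjusted over the list alone), Hsph1 by 2.89 ± 0.21, with a median of 0.86 (adjusted p = 2.86e-08, and adjusted p = 0.0198 with an estimated correlation). Ribosome biogenesis genes, such as Nolc1 at 2.21 ± 0.14, rose in 18 of 20 cases (19 adjusted over the list alone). Their median of 0.69 had an adjusted p = 1.69e-14 and an adjusted p = 0.0684 with an estimated correlation. Among 16 glucocorticoid-responsive genes 9 rose, Pdk4 by 3.05 ± 0.34, and Tsc22d3 fell by 0.52 ± 0.10 (10 and 1 adjusted over the list alone; median 0.63, adjusted p = 4.25e-05, and adjusted p = 0.152 with an estimated correlation).

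Lower after 2 h of E2 were 14 of 20 genes of the IGF and insulin axis, with Stc1, a secreted glycoprotein, falling by 3.03 ± 0.21, while Igf1 and Stc2 rose (15 lower and 2 higher adjusted over the list alone). That list had a median of -0.53 (adjusted p = 0.000812, and adjusted p = 0.0684 with an estimated correlation). FOXO target genes, which FOXO factors switch on when insulin or IGF1 signalling is low, fell in 13 of 21 cases and rose in 4 (14 and 4 adjusted over the list alone). Sesn1 fell by 3.05 ± 0.13 and Txnip by 2.63 ± 0.25, whereas Pdk4 and Gadd45a (1.86 ± 0.12) rose, and the list median was -0.36 (adjusted p = 0.00475, and adjusted p = 0.288 with an estimated correlation). Stromal marker genes fell in 10 of 13 cases, Nr2f2 by 2.66 ± 0.09, and rose in 2, Col6a3 by 2.30 ± 0.16 most (10 and 2 adjusted over the list alone). Their median was -0.71 (adjusted p = 0.00248, and adjusted p = 0.279 with an estimated correlation). Over all genes 12050 passed, 5189 higher and 6861 lower (43.1% higher, and 60.2% with centring). At least 2-fold moved 1608, of which 1593 had the same sign in each of the 3 mouse sets. The same sets picked these genes, here and below, so this is no separate test.

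At 24 h after E2, genes of proliferation and secretion rose in wild-type uterus. Mki67, a marker of proliferating cells, rose by 4.44 ± 0.27 (adjusted p = 5.46e-17, 9 E2 and 8 vehicle arrays), Ube2c by 5.03 ± 0.31 and Ccnb2, the cyclin B2 gene, by 4.68 ± 0.21. Sprr2f, of the small proline-rich proteins of epithelia, rose by 9.47 ± 0.42, Sprr1a by 7.53 ± 0.34 and Ltf, the lactoferrin gene, by 3.87 ± 0.32. Inmt fell by 4.11 ± 0.26, Igfbp3, an IGF binding protein gene, by 4.03 ± 0.19 and Tgfbi fell by 3.86 ± 0.21. Igf1r fell by 1.74 ± 0.10 and Irs2 by 2.28 ± 0.19, while Greb1 was 0.57 ± 0.11 above vehicle (adjusted p = 1.57e-05).

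All 22 mitosis genes rose 24 h after E2 (22 adjusted over the list alone), from 1.13 ± 0.11 for Cenpa to 5.03 ± 0.31 for Ube2c, with a median of 3.17 (adjusted p = 7.12e-23, and adjusted p = 0.0317 with an estimated correlation). All 24 DNA replication genes rose as well (24 adjusted over the list alone), Mcm3 by 3.27 ± 0.14, with a median of 1.68 (adjusted p = 2.39e-22, and adjusted p = 0.0283 with an estimated correlation). Of 17 late E2-induced secretory genes 14 rose (15 adjusted over the list alone), and Lyz1 fell by 0.74 ± 0.26 (median 2.80, adjusted p = 1.23e-11, and adjusted p = 0.00206 with an estimated correlation). Epithelial marker genes rose in 15 of 17 cases (15 adjusted over the list alone), Elf3 by 3.90 ± 0.14, and Wnt7a fell by 0.81 ± 0.15. Their median was 2.01 (adjusted p = 7.62e-12, and adjusted p = 0.0228 with an estimated correlation). The 15 cholesterol synthesis genes all rose (15 adjusted over the list alone), Fdps by 4.67 ± 0.27. Their median was 2.01 (adjusted p = 1.55e-14, and adjusted p = 0.0556 with an estimated correlation).

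Unfolded protein response genes rose in 15 of 18 cases at 24 h of E2, the chaperone gene Calr by 2.32 ± 0.17, while Ddit3 fell by 0.90 ± 0.12 and Dnajb9 by 0.26 ± 0.10 (15 and 2 adjusted over the list alone). The list median was 1.00 (adjusted p = 5.79e-08, and adjusted p = 0.0766 with an estimated correlation). FOXO target genes fell in 17 of 21 cases, Irs2 and Txnip (by 2.28 ± 0.25) most, and Gadd45a rose by 0.37 ± 0.12 (17 and 1 adjusted over the list alone). Their median was -0.59 (adjusted p = 6.3e-06, and adjusted p = 0.0711 with an estimated correlation). Circadian clock genes fell in 12 of 15 cases, Hlf by 1.76 ± 0.12, and Bhlhe40 rose by 1.09 ± 0.13 (12 and 1 adjusted over the list alone). Their median was -0.86 (adjusted p = 0.000132, and adjusted p = 0.0556 with an estimated correlation). T and NK cell markers fell in 11 of 13 cases (11 adjusted over the list alone; median -0.39, adjusted p = 0.0362, and adjusted p = 0.522 with an estimated correlation). Smooth muscle genes rose in 7 of 12 cases and fell in 2 (7 and 2 adjusted over the list alone; median 0.35, adjusted p = 0.0413, and adjusted p = 0.611 with an estimated correlation). After quantile normalization neither list passed (adjusted p = 0.0949 and 0.438), nor did smooth muscle with centring (adjusted p = 0.076). Over all genes 16942 passed, 7396 higher and 9546 lower (43.7% higher, and 56.5% with centring). At least 2-fold moved 2644, of which 2623 had the same sign in each set. In the ERaUtcKO littermates alone, the median of all genes was -0.16 for E2 and -0.14 for IGF1 at 24 h.

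IGF1 at 2 h lowered Fbxo32, a ubiquitin ligase gene switched on by FOXO factors, by 5.02 ± 0.24 in wild-type uterus (adjusted p = 5.2e-19, 7 IGF1 and 8 vehicle arrays). Klhl24 fell by 4.04 ± 0.17, Irs2 by 2.62 ± 0.20 and Igf1r by 0.93 ± 0.11. Tnfrsf12a, the TWEAK receptor gene, rose by 4.28 ± 0.26, and the ERK pathway inhibitor genes Spry4 and Dusp6 by 3.72 ± 0.23 and 3.09 ± 0.16. Greb1 did not pass (0.12 ± 0.11, adjusted p = 0.456), whereas Cdkn1a rose by 2.78 ± 0.25 and Vegfa by 2.54 ± 0.16.

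Of 21 FOXO target genes 16 fell 2 h after IGF1 and 0 rose (16 and 0 adjusted over the list alone), and Sesn1 fell by 2.93 ± 0.14. The median was -0.94 (adjusted p = 1.89e-11, and adjusted p = 0.0115 with an estimated correlation). All 10 heat-shock genes rose (10 adjusted over the list alone), Hsph1 by 3.08 ± 0.23 (median 1.05, adjusted p = 1.89e-11, and adjusted p = 0.00991 with an estimated correlation). All 17 genes of the ATF4 and amino acid response rose (17 adjusted over the list alone), Mthfd2, of mitochondrial folate metabolism, by 2.86 ± 0.14. Their median of 1.5 had an adjusted p = 1.88e-15 and an adjusted p = 0.0533 with an estimated correlation. Ribosome biogenesis genes rose in 19 of 20 cases (19 adjusted over the list alone), Nolc1 by 1.98 ± 0.15 (median 0.79, adjusted p = 1.53e-16, and adjusted p = 0.0533 with an estimated correlation). Immediate-early genes rose in 16 of 21 cases (17 adjusted over the list alone), Nr4a1 by 3.77 ± 0.47 (median 1.18, adjusted p = 1.11e-10, and adjusted p = 0.0665 with an estimated correlation).

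Cholesterol synthesis genes rose in 14 of 15 cases 2 h after IGF1 (14 adjusted over the list alone), Cyp51 by 2.45 ± 0.22, with a median of 0.87 (adjusted p = 3e-08, and adjusted p = 0.149 with an estimated correlation). ERK pathway feedback genes rose in 9 of 16 cases and Il2ra fell by 0.26 ± 0.07 (9 and 1 adjusted over the list alone; median 0.33, adjusted p = 0.000553, and adjusted p = 0.0533 with an estimated correlation). The early E2-responsive uterine genes rose in 11 of 20 cases, Ccn1 by 3.38 ± 0.41 and Cdkn1a as above, and Sox4 fell by 2.55 ± 0.11 (11 and 1 adjusted over the list alone). Their median was 0.42 (adjusted p = 0.000457, and adjusted p = 0.0665 with an estimated correlation). Over all genes 10823 passed, 5100 higher and 5723 lower (47.1% higher, and 63.4% with centring). At least 2-fold moved 1176, of which 1157 had the same sign in each set.

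At 24 h after IGF1, Igfbp5, an IGF binding protein gene, rose by 4.03 ± 0.19 (adjusted p = 7.82e-19, 9 IGF1 and 8 vehicle arrays), Mki67 by 2.81 ± 0.27 and Idi1, of cholesterol synthesis, by 3.00 ± 0.23. Lgals1, the galectin 1 gene, rose by 2.79 ± 0.15. Galnt15 fell by 3.49 ± 0.18, Lepr, the leptin receptor gene, by 3.03 ± 0.14, Irs2 by 1.87 ± 0.19 and Igf1r by 1.27 ± 0.10. Alb, the albumin gene, fell by 3.94 ± 0.71 over the 3 sets. In the Ex3aERKO littermates Alb differed by -0.10 and Irs2 by -0.62 (Irs2 adjusted p = 0.483). Ltf fell by 0.81 ± 0.32 over the 3 sets (adjusted p = 0.0399), from 9.44 to 7.75 in C57, but had means of 8.83 under vehicle and 8.99 after IGF1 in the Ex3aERKO littermates.

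Mitosis genes rose in 21 of 22 cases 24 h after IGF1 (22 adjusted over the list alone), Top2a by 2.71 ± 0.27 and Bub1b by 0.36 ± 0.14, with a median of 1.49 (adjusted p = 3.67e-18, and adjusted p = 0.0606 with an estimated correlation). All 24 DNA replication genes rose (24 adjusted over the list alone), Rrm2 by 1.56 ± 0.12 (median 0.77, adjusted p = 4.37e-18, and adjusted p = 0.0521 with an estimated correlation). All 15 cholesterol synthesis genes rose (15 adjusted over the list alone; median 1.22, adjusted p = 2.89e-16, and adjusted p = 0.0521 with an estimated correlation). Smooth muscle genes rose in 11 of 12 cases (11 adjusted over the list alone), the actin gene Actg2 by 2.57 ± 0.16 (median 0.84, adjusted p = 9.89e-10, and adjusted p = 0.0751 with an estimated correlation). Macrophage markers rose in 6 of 14 cases and fell in 1 (6 and 1 adjusted over the list alone; median 0.27, adjusted p = 0.0245, and adjusted p = 0.559 with an estimated correlation), and did not pass after quantile normalization (adjusted p = 0.0651). Extracellular matrix genes rose in 15 of 19 cases, Col1a1 by 2.25 ± 0.18, and fell in 3, among them Mmp11 by 1.47 ± 0.14 (15 and 3 adjusted over the list alone). Their median was 0.73 (adjusted p = 3.71e-07, and adjusted p = 0.125 with an estimated correlation). FOXO target genes fell in 17 of 21 cases (17 adjusted over the list alone; median -0.54, adjusted p = 1.84e-08, and adjusted p = 0.0521 with an estimated correlation).

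Of the 17 late E2-induced secretory genes, only Gpx2 (0.78 ± 0.20) and Muc1 (0.51 ± 0.15) rose 24 h after IGF1 and Ltf fell (2 and 0 adjusted over the list alone). The list as a whole did not pass (median -0.08, mean 0.01, adjusted p = 0.625). Over all genes 12329 passed, 5819 higher and 6510 lower (47.2% higher, and 60.9% with centring). At least 2-fold moved 875, of which 860 had the same sign in each set.

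Both hormones were compared at 2 h in wild types. E2 was above IGF1 for Klk1 by 8.45 ± 0.30, for Mad2l1 by 6.47 ± 0.16 and for Pgf by 5.73 ± 0.11. The difference was -4.67 ± 0.27 for Cd248 and -3.08 ± 0.32 for Cldn1. Early E2-responsive uterine genes were higher with E2 in 17 of 20 cases and lower in 1, Sox4 at -0.92 ± 0.11 (17 and 1 adjusted over the list alone). Their median difference was 2.02 (adjusted p = 6.12e-24, and adjusted p = 1.43e-06 with an estimated correlation). Progesterone-responsive uterine genes were lower with E2 in 8 of 13 cases, Nr2f2 at -2.59 ± 0.09, and higher in 1, Errfi1 at 1.79 ± 0.13 (9 and 1 adjusted over the list alone; median -0.45, adjusted p = 1.72e-05, and adjusted p = 0.027 with an estimated correlation). Cholesterol synthesis genes were lower with E2 than with IGF1 in 12 of 15 cases and higher in 1 (12 and 1 adjusted over the list alone), Insig1 at -1.76 ± 0.21 (median -0.80, adjusted p = 1.07e-06, and adjusted p = 0.357 with an estimated correlation). ATF4 and amino acid response genes were lower with E2 in 12 of 17 cases, Mthfd2 at -1.87 ± 0.14, and higher in 1, the transporter gene Slc7a5 at 2.20 ± 0.22 (13 and 1 adjusted over the list alone). Their median was -0.68 (adjusted p = 1.08e-05, and adjusted p = 0.379 with an estimated correlation). In all 6620 genes differed, 2895 higher and 3725 lower with E2, and 761 did so by at least 2-fold, 760 of them with the same sign in the 3 sets.

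At 24 h the secretory and epithelial genes separated both hormones. Sprr2f was 8.94 ± 0.41 higher with E2 than with IGF1 and Klk1 was 5.46 ± 0.28 higher, while Tgfbi differed by -3.43 ± 0.20 and S100a8, of the calgranulins of myeloid cells, by -2.43 ± 0.62. Late E2-induced secretory genes were higher with E2 in 15 of 17 cases (15 higher and 1 lower adjusted over the list alone; median 2.93, adjusted p = 5.48e-25, and adjusted p = 2.03e-06 with an estimated correlation). Epithelial marker genes were higher with E2 in 15 of 17 cases (15 adjusted over the list alone), Elf3 by 3.66 ± 0.14, with a median of 1.61 (adjusted p = 2.7e-24, and adjusted p = 0.000228 with an estimated correlation). All 22 mitosis genes were higher with E2 (22 adjusted over the list alone), Ube2c by 2.91 ± 0.30 (median 1.64, adjusted p = 3.14e-29, and adjusted p = 0.00841 with an estimated correlation). Clock genes were lower with E2 in 11 of 15 cases, Nr1d1 at -1.58 ± 0.16, and higher in 3, among them Bhlhe40 at 0.99 ± 0.13 (11 and 3 adjusted over the list alone; median -0.86, adjusted p = 4.36e-07, and adjusted p = 0.00841 with an estimated correlation). Marker lists lower with E2 were smooth muscle (median -0.46, adjusted p = 3.55e-05, 7 of 12 genes), mesothelium (-0.68, adjusted p = 0.0058, 6 of 8, with 1 higher), macrophages (-0.36, adjusted p = 0.00631, 6 of 14, with 1 higher), T and NK cells (-0.27, adjusted p = 0.00806, 5 of 13) and endothelium (-0.20, adjusted p = 0.0125, 6 of 11). None passed with an estimated correlation (adjusted p from 0.248 to 0.362). In all 8484 genes differed, 4608 higher and 3876 lower with E2, and 569 did so by at least 2-fold, each with the same sign in the 3 sets.

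**Figure D1:**
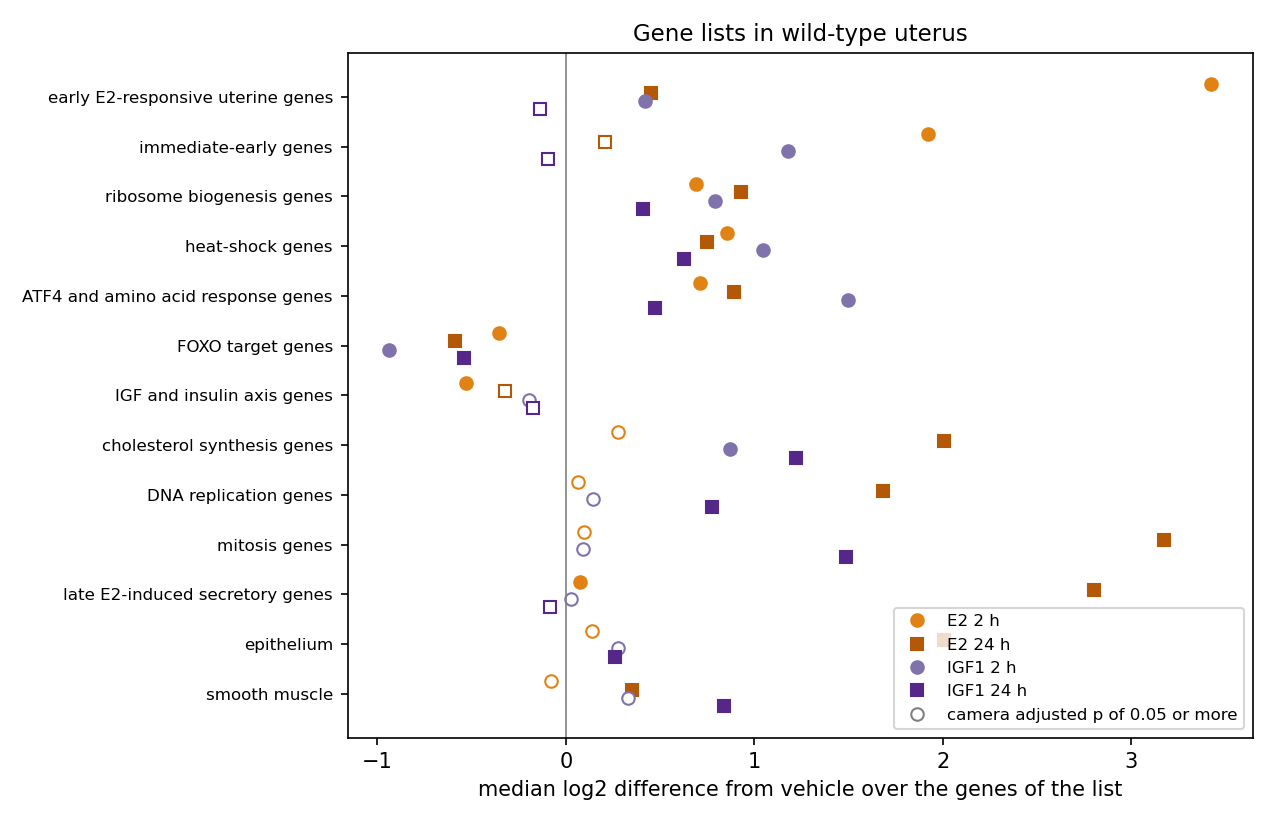
Median log2 difference of 13 gene lists in 4 wild-type comparisons against vehicle, on 1 axis per list, with open symbols where the list did not pass at the preset correlation. The late E2-induced secretory genes lie at 2.80 after 24 h of E2 and at -0.08 after 24 h of IGF1.

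The responses to both hormones overlapped. At 2 h 7744 genes moved the same way (3480 higher and 4264 lower), against 878 and 1303 if the calls were independent, and 476 moved in opposite ways. At 24 h 10744 moved the same way (5132 higher and 5612 lower), against 1428 and 2062, and 182 in opposite ways. Both responses share their vehicle arrays, which alone links them: in 20 simulations with no effect the correlation across genes was 0.50 and 0.53. With 4 separate vehicle arrays for each hormone, it was 0.64 and 0.80 (0.69 and 0.84 when shared). Genes are not independent replicates, so no p is given for these correlations.

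Under vehicle Coch (cochlin) was above littermates by 3.60 ± 0.32 (adjusted p = 5.33e-06, 2 and 2 arrays) in Ex3aERKO and 3.39 ± 0.27 (adjusted p = 6.59e-08, 3 and 3 arrays) in ERaUtcKO. Single immunoglobulin genes fell most, Ighv3-6 by 5.48 ± 1.41 in Ex3aERKO and Igkv10-95 by 4.63 ± 0.77 in ERaUtcKO. After 2 h of E2 Ighv3-6 was higher in Ex3aERKO (11.13) than in littermates (9.52). Slc7a11 fell by 4.62 ± 0.40 and 3.92 ± 0.34, and the chemokine gene Cxcl15 by 4.55 ± 0.82 and 4.11 ± 0.49. In Ex3aERKO Rxfp1, the relaxin receptor gene, fell by 4.33 ± 0.24 and Igf1 by 1.13 ± 0.29 (adjusted p = 0.0395). In ERaUtcKO Igf1r rose by 0.92 ± 0.14 and Pgr fell by 0.95 ± 0.17. In the other line Igf1 (-0.51), Igf1r (0.55) and Pgr (-0.29) did not pass. Greb1 was lower in both, at -0.89 ± 0.17 and -0.63 ± 0.12, the former a lower limit of the fall because Ex3aERKO lay at background.

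In Ex3aERKO 10 of 17 epithelial marker genes were higher under vehicle (12 adjusted over the list alone), Krt7 by 1.79 ± 0.32 (median 1.01, adjusted p = 4.17e-12, and adjusted p = 0.239 with an estimated correlation). Extracellular matrix genes were lower in 6 of 19 cases (6 adjusted over the list alone), Thbs1 at -2.32 ± 0.27 (median -0.22, adjusted p = 6.29e-06, and adjusted p = 0.295 with an estimated correlation). Of 13 stromal marker genes Col6a3 (-1.59 ± 0.36) and Hoxa10 (-0.81 ± 0.21) were lower, and 5 adjusted over the list alone (median -0.56, adjusted p = 0.000179, and adjusted p = 0.379 with an estimated correlation). Smooth muscle and macrophage markers were lower as lists (medians -0.52 and -0.41, adjusted p = 0.0182 and 0.00212, and adjusted p = 0.702 and 0.508 with an estimated correlation), with 0 of 12 and 0 of 14 called in limma and 0 adjusted over each list alone. After quantile normalization smooth muscle did not pass (adjusted p = 0.0696). In ERaUtcKO 5 of 20 IGF and insulin axis genes were higher, Stc1 by 2.40 ± 0.40 (8 higher and 3 lower adjusted over the list alone; median 0.10, adjusted p = 0.000529, and adjusted p = 0.0363 with an estimated correlation). Epithelial, smooth muscle and mesothelial markers were higher as lists in ERaUtcKO (medians 0.35, 0.31 and 0.32, adjusted p = 0.00281, 0.000726 and 0.0241), with 1, 1 and 0 genes called. With an estimated correlation each had an adjusted p = 0.71, and with quantile normalization the mesothelial one an adjusted p = 0.0617. Early E2-responsive genes were lower there in 3 of 20 cases (5 adjusted over the list alone), Sox4 at -1.23 ± 0.20 (median -0.29, adjusted p = 0.00408, and adjusted p = 0.107 with an estimated correlation).

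Over all genes 891 differed under vehicle in Ex3aERKO, 470 higher and 421 lower, and 1258 in ERaUtcKO, 607 higher and 651 lower (48.3% higher, 63.7% when each array was centred on its median and 58.4% after quantile normalization). Single arrays moved these counts, from 165 to 770 in Ex3aERKO and from 627 to 2083 in ERaUtcKO. With only the arrays compared in the model, 215 and 445 genes passed.

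E2 at 2 h was also tested in the knockout lines. In Ex3aERKO Zbtb16, a zinc finger gene induced by glucocorticoids, rose by 4.03 ± 0.59 (adjusted p = 0.00683, 2 and 2 arrays) and Sult1d1 by 3.10 ± 0.42, while Hpgds, a prostaglandin D synthase gene, fell by 2.89 ± 0.40. In ERaUtcKO Zbtb16 rose by 3.65 ± 0.27 (adjusted p = 3.23e-08, 3 and 3 arrays) and Sult1d1 by 1.98 ± 0.26. Greb1 rose by 1.66 ± 0.12 (adjusted p = 3.23e-08) in ERaUtcKO and had a difference of -0.08 ± 0.17 (adjusted p = 0.984) in Ex3aERKO. Fos did not pass in either line (0.25, adjusted p = 0.79 in ERaUtcKO).

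Glucocorticoid-responsive genes rose in 5 of 16 cases in Ex3aERKO (14 adjusted over the list alone), Tsc22d3 by 1.74 ± 0.31, with a list median of 1.17 (adjusted p = 1.94e-25, and adjusted p = 0.00203 with an estimated correlation). In ERaUtcKO 6 of 16 rose (12 adjusted over the list alone), Mt2 by 1.23 ± 0.28, with a median of 0.91 (adjusted p = 1.98e-27, and adjusted p = 3.74e-05 with an estimated correlation). Of the 20 early E2-responsive genes 7 rose in ERaUtcKO (13 adjusted over the list alone), among them Cdkn1a by 1.56 ± 0.33 and Vegfa by 0.75 ± 0.13 (median 0.74, adjusted p = 1.11e-23, and adjusted p = 5.13e-07 with an estimated correlation). In ERaUtcKO the adipocyte markers had a median of 1.35 with 0 of 10 called in limma and 0 adjusted over the list alone (adjusted p = 6.24e-07, and adjusted p = 0.267 with an estimated correlation), and of the 14 macrophage markers Mertk rose by 0.71 ± 0.14 (2 adjusted over the list alone; median 0.42, adjusted p = 1.35e-07, and adjusted p = 0.0585 with an estimated correlation). Of the early E2-responsive genes in Ex3aERKO 0 of 20 passed in limma (2 higher and 1 lower adjusted over the list alone), with a list median of 0.10 (adjusted p = 0.149). Heat-shock and unfolded protein response genes were higher as lists in both lines. In Ex3aERKO the medians were 0.40 and 0.39 (each adjusted p = 1.77e-07, and adjusted p = 0.0928 and 0.222 with an estimated correlation), with 0 called in limma and 5 of 10 and 2 of 18 adjusted over the list alone. In ERaUtcKO they were 0.32 and 0.31 (adjusted p = 4.33e-09 and 4.34e-10, and adjusted p = 0.00607 and 0.0275 with an estimated correlation), with 4 and 2 called (6 and 4 adjusted over the list alone). T and NK cell markers had medians of 0.18 in both lines (adjusted p = 0.000352 and 0.000729, and adjusted p = 0.222 and 0.294 with an estimated correlation). Macrophage markers in Ex3aERKO had a median of 0.10 and B and plasma cell markers in ERaUtcKO one of 0.26 (adjusted p = 0.00393 and 5.95e-05, and adjusted p = 0.427 and 0.106 with an estimated correlation). Of these 4 limma called 0 genes (0, 0, 2 and 1 adjusted over the list alone). Over all genes 45 changed in Ex3aERKO, 35 higher and 10 lower, and 148 in ERaUtcKO, 120 higher and 28 lower (81.1% higher, and 70.4% after quantile normalization). Without single arrays the former count ran from 5 to 53, with a replicate block it was 9, and with only the arrays compared it was 0 in limma (1701 at an unadjusted p under 0.05). The latter ran from 49 to 95, and was 14 with only the arrays compared.

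The interaction test compared the early E2 response between genotypes. Klk1 responded by 9.32 in Ex3aERKO littermates and by 0.11 in Ex3aERKO, a difference of -9.21 ± 0.58 (adjusted p = 9.55e-09), and by 8.57 and 1.56 in the ERaUtcKO experiment (-7.01 ± 0.48, adjusted p = 9.19e-10). Greb1 differed by -4.91 ± 0.22 and -2.83 ± 0.17, Fos, at background except in littermates given E2, by -3.96 ± 0.28 and -3.34 ± 0.26, and Vegfa by -4.14 ± 0.41 and -3.10 ± 0.19. Irs2, which fell in the littermates (-1.92 and -2.61), differed by 2.10 ± 0.59 (adjusted p = 0.0286) and 2.53 ± 0.33, and Rgs2 by 4.87 ± 0.50 and 3.76 ± 0.27. The response of the early E2-responsive genes was lower in 16 of 20 cases and higher in 1 in Ex3aERKO (16 and 1 adjusted over the list alone; median -3.12, adjusted p = 1.38e-22, and adjusted p = 1.2e-05 with an estimated correlation). In ERaUtcKO it was lower in 15 and higher in 1 (15 and 1 adjusted over the list alone; median -2.29, adjusted p = 6.63e-22, and adjusted p = 9.56e-07 with an estimated correlation). Immediate-early genes responded less in 16 of 21 cases in Ex3aERKO (18 adjusted over the list alone), Nr4a1 by -4.24 ± 0.37 (median -1.78, adjusted p = 5.73e-21, and adjusted p = 0.00603 with an estimated correlation). In ERaUtcKO it was 18 of 21 (19 adjusted over the list alone; median -1.70, adjusted p = 3.86e-22, and adjusted p = 0.0263 with an estimated correlation). In all 2841 genes differed in their response in Ex3aERKO (1380 higher and 1461 lower). In ERaUtcKO 4154 did (2020 higher and 2134 lower, 48.6% higher, and 31.9% with centring). Without littermate vehicle replicate 3 the Ex3aERKO count was 1810.

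At 24 h after E2 neither knockout line had a called gene. Limma called 0 genes in Ex3aERKO (4166 at an unadjusted p under 0.05) and 0 in ERaUtcKO (1151 unadjusted). Mki67 had a difference of -0.16 (adjusted p = 0.949) in Ex3aERKO and -0.24 (adjusted p = 1) in ERaUtcKO. Of the 22 mitosis genes 0 were called in each line, and 0 adjusted over the list alone, with list medians of 0.08 (adjusted p = 0.969) and -0.06 (adjusted p = 0.701). Of the 17 late E2-induced secretory genes 0 were called in Ex3aERKO (1 adjusted over the list alone; median 0.29, adjusted p = 0.179), with Sprr2f at 3.28 ± 1.46 and Ltf at 3.01 ± 1.70. In ERaUtcKO 0 were called (0 adjusted over the list alone; median -0.08, mean -0.14, adjusted p = 0.603). Of the 33 lists 3 passed in each line and 0 with an estimated correlation. The early E2-responsive genes in Ex3aERKO had a median of 0.51 with 0 of 20 called (0 adjusted over the list alone; adjusted p = 0.0027, and adjusted p = 0.15 with an estimated correlation), and the epithelial markers in ERaUtcKO one of 0.27 with 0 of 17 called (0 adjusted over the list alone; adjusted p = 3.99e-06, and adjusted p = 0.926 with an estimated correlation). Changes of log2 1 put into simulated data were recovered in 58.2% of cases for this comparison in Ex3aERKO and 88.1% in ERaUtcKO. Without single arrays up to 9 genes passed in Ex3aERKO and up to 1 in ERaUtcKO, and after quantile normalization 16 did in Ex3aERKO.

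The late E2 response differed between genotypes in Ube2c by -6.00 ± 0.88 (adjusted p = 0.000145) in Ex3aERKO and -6.01 ± 0.45 (adjusted p = 2.34e-09) in ERaUtcKO, and in Mki67 by -5.25 ± 0.96 and -5.06 ± 0.69. Sprr1a differed by -6.89 ± 1.44 and -8.67 ± 0.64, and Igfbp3, which fell in the littermates, by 4.2 ± 0.61 and 3.54 ± 0.30. Igf1r responded by -2.06 in Ex3aERKO littermates and -0.38 in Ex3aERKO (1.69 ± 0.28, adjusted p = 0.000417) and by -1.41 and -0.01 in the ERaUtcKO experiment (1.40 ± 0.20, adjusted p = 9.62e-06). Mitosis genes responded less in 21 of 22 cases in Ex3aERKO (21 adjusted over the list alone; median -3.05, adjusted p = 2.8e-23, and adjusted p = 0.0629 with an estimated correlation). In ERaUtcKO all 22 did (22 adjusted over the list alone; median -3.25, adjusted p = 6.33e-25, and adjusted p = 0.0426 with an estimated correlation). The secretory genes responded less in 11 of 17 cases in Ex3aERKO (12 adjusted over the list alone; median -2.69, adjusted p = 1.34e-09, and adjusted p = 0.0503 with an estimated correlation). In ERaUtcKO 13 of 17 did (13 adjusted over the list alone; median -3.02, adjusted p = 1.27e-15, and adjusted p = 0.0106 with an estimated correlation). Epithelial markers responded less in 12 of 17 cases in Ex3aERKO (13 lower and 1 higher adjusted over the list alone; median -2.29, adjusted p = 4.15e-12, and adjusted p = 0.0503 with an estimated correlation). In ERaUtcKO 12 did and 1 responded more (13 and 1 adjusted over the list alone; median -1.73, adjusted p = 2.3e-10, and adjusted p = 0.0426 with an estimated correlation). Cholesterol synthesis genes responded less in 14 of 15 cases in Ex3aERKO (15 adjusted over the list alone), Fdps by -5.19 ± 0.53, with a median of -2.14 (adjusted p = 2.75e-17, and adjusted p = 0.0503 with an estimated correlation). In ERaUtcKO all 15 did (15 adjusted over the list alone; median -1.97, adjusted p = 1.07e-20, and adjusted p = 0.0151 with an estimated correlation).

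Over all genes the late E2 response differed for 5063 in Ex3aERKO, 1911 higher and 3152 lower (37.7% higher, and 24.2% when each array was centred on its median), and for 3356 without littermate vehicle replicate 3. In ERaUtcKO it differed for 9907, 5225 higher and 4682 lower (52.7% higher, and 34.3% with centring), with a median over all genes of 0.13.

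IGF1 at 2 h changed many genes in both knockout lines. Fbxo32 fell by 5.06 ± 0.54 (adjusted p = 4.3e-06, 2 and 2 arrays) in Ex3aERKO and by 5.58 ± 0.30 (adjusted p = 2.88e-12, 3 and 3 arrays) in ERaUtcKO. Klhl24 fell by 4.34 ± 0.28 and 3.88 ± 0.27, and Irs2 by 2.07 ± 0.44 and 2.41 ± 0.23. Spry4 rose by 5.0 ± 0.47 and 4.66 ± 0.24, Tnfrsf12a by 4.42 ± 0.32 and 4.93 ± 0.34, and Egr1 by 4.30 ± 0.47 and 4.94 ± 0.35. Vegfa rose by 3.25 ± 0.30 and 2.88 ± 0.13. Greb1 had a difference of -0.09 (adjusted p = 0.803) in Ex3aERKO and -0.00 (adjusted p = 0.994) in ERaUtcKO.

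The ATF4 and amino acid response genes rose after 2 h of IGF1 in 16 of 17 cases in Ex3aERKO (17 adjusted over the list alone), Chac1 by 3.88 ± 0.40 (median 2.08, adjusted p = 2.38e-17, and adjusted p = 0.0472 with an estimated correlation). In ERaUtcKO all 17 rose (17 adjusted over the list alone), Mthfd2 by 3.69 ± 0.15 (median 1.94, adjusted p = 2.74e-21, and adjusted p = 0.00419 with an estimated correlation). FOXO target genes fell in 12 of 21 cases in Ex3aERKO, Sesn1 by 2.95 ± 0.29, and Gadd45a rose by 0.78 ± 0.24 (14 and 1 adjusted over the list alone; median -0.81, adjusted p = 1.63e-08, and adjusted p = 0.0234 with an estimated correlation). In ERaUtcKO 15 fell, and Gadd45a and Bcl6 rose (16 and 2 adjusted over the list alone; median -1.05, adjusted p = 4.64e-09, and adjusted p = 0.00419 with an estimated correlation). Immediate-early genes rose in 14 of 21 cases in Ex3aERKO (14 adjusted over the list alone; median 0.89, adjusted p = 2.98e-10, and adjusted p = 0.0472 with an estimated correlation). In ERaUtcKO 17 rose (19 adjusted over the list alone; median 1.33, adjusted p = 4.39e-16, and adjusted p = 0.0321 with an estimated correlation). Over all genes 4730 changed in Ex3aERKO (2594 higher and 2136 lower, 54.8% higher, and 46.0% after quantile normalization). In ERaUtcKO 8824 did (3936 higher and 4888 lower, 44.6% higher, and 54.3% with centring). The Ex3aERKO count was 2943 without vehicle replicate 2 and 482 with only the arrays compared.

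The 2 h response to IGF1 differed from that of the littermates in 154 genes of ERaUtcKO, 100 higher and 54 lower. Sgms2, a sphingomyelin synthase gene, rose by 3.41 in littermates and 0.93 in ERaUtcKO (-2.48 ± 0.21, adjusted p = 8.23e-07), the amino acid transporter gene Slc6a14 responded by 2.48 and 0.31 (-2.17 ± 0.20, adjusted p = 4e-06) and the chemokine gene Ccl28 by 1.79 and -0.21 (-2.0 ± 0.37, adjusted p = 0.0108). In the other direction, Thbs1 rose by 2.21 in littermates and 5.14 in ERaUtcKO (2.93 ± 0.56, adjusted p = 0.0122), Egr1 by 2.28 and 4.94 (2.66 ± 0.52, adjusted p = 0.0167), and Slc7a11 responded by -0.27 and 2.20 (2.47 ± 0.51, adjusted p = 0.0254). ATF4 and amino acid response genes responded more in ERaUtcKO in 8 of 17 cases (13 adjusted over the list alone; median 0.84, adjusted p = 6.15e-21, and adjusted p = 0.00965 with an estimated correlation). Immediate-early genes did so in 3 of 21 cases (3 adjusted over the list alone), Egr1, Egr2 (1.72 ± 0.20) and Fosl1 (1.00 ± 0.22), with a median of 0.56 (adjusted p = 2.86e-09, and adjusted p = 0.335 with an estimated correlation). The count of 154 ran from 84 to 204 without single arrays, and was 44 with only the arrays compared. In Ex3aERKO limma called 0 genes for this difference (2247 at an unadjusted p under 0.05), and from 0 to 40 without single arrays. Ribosome biogenesis, cholesterol synthesis, unfolded protein response and heat-shock genes responded less there as lists (medians -0.23, -0.45, -0.32 and -0.28, adjusted p = 0.00726, 0.0327, 0.00922 and 0.0426), with 0 called in limma (0, 0, 0 and 1 lower adjusted over the list alone). The ATF4 and immediate-early lists did not pass (medians 0.04 and -0.05, adjusted p = 0.235 and 0.232), with 0 called in limma (0 and 1 lower adjusted over the list alone). All 6 had an adjusted p = 0.905 with an estimated correlation, and with centring the cholesterol and heat-shock lists did not pass (each adjusted p = 0.0558). The gene test recovered 43.3% of simulated changes of log2 1, so differences of that size were not reliably detectable.

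At 24 h after IGF1 Igfbp5 rose by 3.89 ± 0.47 (adjusted p = 2.25e-05, 3 and 2 arrays) in Ex3aERKO and by 4.03 ± 0.30 (adjusted p = 1.49e-09, 3 and 3 arrays) in ERaUtcKO. Lgals1 rose by 3.67 ± 0.40 and 3.66 ± 0.33, and Mki67 by 2.47 ± 0.64 and 1.48 ± 0.48. Hpgds fell by 5.89 ± 0.37 and 4.70 ± 0.29, Inmt by 5.36 ± 0.70 and 4.39 ± 0.50, Igf1r by 1.80 ± 0.19 and 1.27 ± 0.14, and Irs2 by 2.10 ± 0.40 and 2.40 ± 0.23. In littermates Irs2 differed by -0.62 and -2.69. The liver transcripts Alb and Apoa2 fell in ERaUtcKO by 4.56 ± 1.32 and 4.44 ± 1.32.

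Mitosis genes rose 24 h after IGF1 in 12 of 22 cases in Ex3aERKO (16 adjusted over the list alone; median 0.83, adjusted p = 3.28e-05, and adjusted p = 0.464 with an estimated correlation). In ERaUtcKO 5 rose, and Cenpa fell by 0.38 ± 0.14 (3 and 0 adjusted over the list alone; median 0.43, adjusted p = 0.0364, and adjusted p = 0.813 with an estimated correlation). With centring this list did not pass (adjusted p = 0.0777). Cholesterol synthesis genes rose in 9 of 15 cases in Ex3aERKO (9 adjusted over the list alone; median 0.76, adjusted p = 2.96e-05, and adjusted p = 0.366 with an estimated correlation). In ERaUtcKO 14 of 15 rose (14 adjusted over the list alone; median 0.74, adjusted p = 9.5e-11, and adjusted p = 0.0956 with an estimated correlation). FOXO target genes fell in 10 of 21 cases in Ex3aERKO (13 adjusted over the list alone; median -0.63, adjusted p = 2.54e-07, and adjusted p = 0.0654 with an estimated correlation). In ERaUtcKO 17 fell (17 adjusted over the list alone; median -0.75, adjusted p = 4.14e-08, and adjusted p = 0.02 with an estimated correlation). Over all genes 5598 changed in Ex3aERKO, 3530 higher and 2068 lower (63.1% higher, and 48.8% after quantile normalization). In ERaUtcKO 9765 changed, 5080 higher and 4685 lower (52.0% higher, and 65.2% with centring). The Ex3aERKO count was 2376 without vehicle replicate 2 and 3230 with only the arrays compared.

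The 24 h response to IGF1 differed between Ex3aERKO and littermates in 4 genes. Hpgds went from 9.35 to 8.01 in littermates and from 12.70 to 6.80 in Ex3aERKO (-4.56 ± 0.52, adjusted p = 0.00163). Coch went from 9.03 to 7.89 and 12.62 to 8.68 (-2.80 ± 0.42, adjusted p = 0.0191). Wls, of WNT secretion, went from 11.38 to 11.59 and 13.21 to 11.71 (-1.70 ± 0.21, adjusted p = 0.00283). In each, genotypes lay further apart under vehicle than after IGF1. The fourth was the predicted gene Gm15765 (-1.77 ± 0.26, adjusted p = 0.016). It is outside the naming rule and named after its value was seen. The count ran from 2 to 17 without single arrays, and was 1 with only the arrays compared. Interferon-stimulated genes responded more in Ex3aERKO as a list (median 0.90, adjusted p = 6.06e-12, and 0.132 with an estimated correlation). Isg15 at 1.81 ± 0.39 moved furthest, and 0 of 16 passed in limma (10 adjusted over the list alone). Under vehicle this list was lower in Ex3aERKO (median -0.25, adjusted p = 0.00293, and adjusted p = 0.599 with an estimated correlation). Mesothelial markers responded less (median -1.20, adjusted p = 0.000342, and adjusted p = 0.479 with an estimated correlation) and cytokine genes more (median 0.30, adjusted p = 0.000127, and adjusted p = 0.132 with an estimated correlation), with 0 called in limma (2 of 8 lower and 6 of 23 higher adjusted over the list alone). The 22 mitosis genes had a median of -0.37 (adjusted p = 0.00703, and 0.888 with an estimated correlation). The 15 cholesterol synthesis genes had one of -0.01 (adjusted p = 0.764). Of both limma called 0 genes (0 adjusted over each list alone). Limma gave 2390 genes at an unadjusted p under 0.05 in this comparison.

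In ERaUtcKO the 24 h response to IGF1 differed in 15 genes, 4 higher and 11 lower. The share higher was 26.7%, 6.25% with centring and 10% after quantile normalization. Hpgds went from 10.26 to 8.28 in littermates and from 12.34 to 7.64 in ERaUtcKO (-2.71 ± 0.41, adjusted p = 0.00851). The cholesterol synthesis genes Sqle (3.37 in littermates and 1.97 in ERaUtcKO), Nsdhl (2.03 and 0.65) and Fdft1 (1.80 and 0.45) rose less, by differences of -1.39 ± 0.25, -1.38 ± 0.23 and -1.35 ± 0.24. Of the 15 genes of that list 4 responded less (13 adjusted over the list alone; median -1.05, adjusted p = 7.51e-25, and adjusted p = 0.0114 with an estimated correlation). The mitosis genes had a median of -1.03 (adjusted p = 1.47e-24, and adjusted p = 0.151 with an estimated correlation), with 0 of 22 called in limma and 20 lower adjusted over the list alone, and Ube2c at -1.92 ± 0.45. Limma gave 3457 genes at an unadjusted p under 0.05. The count of 15 ran from 3 to 163 without single arrays, and was 4 with a replicate block.

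**Figure D2:**
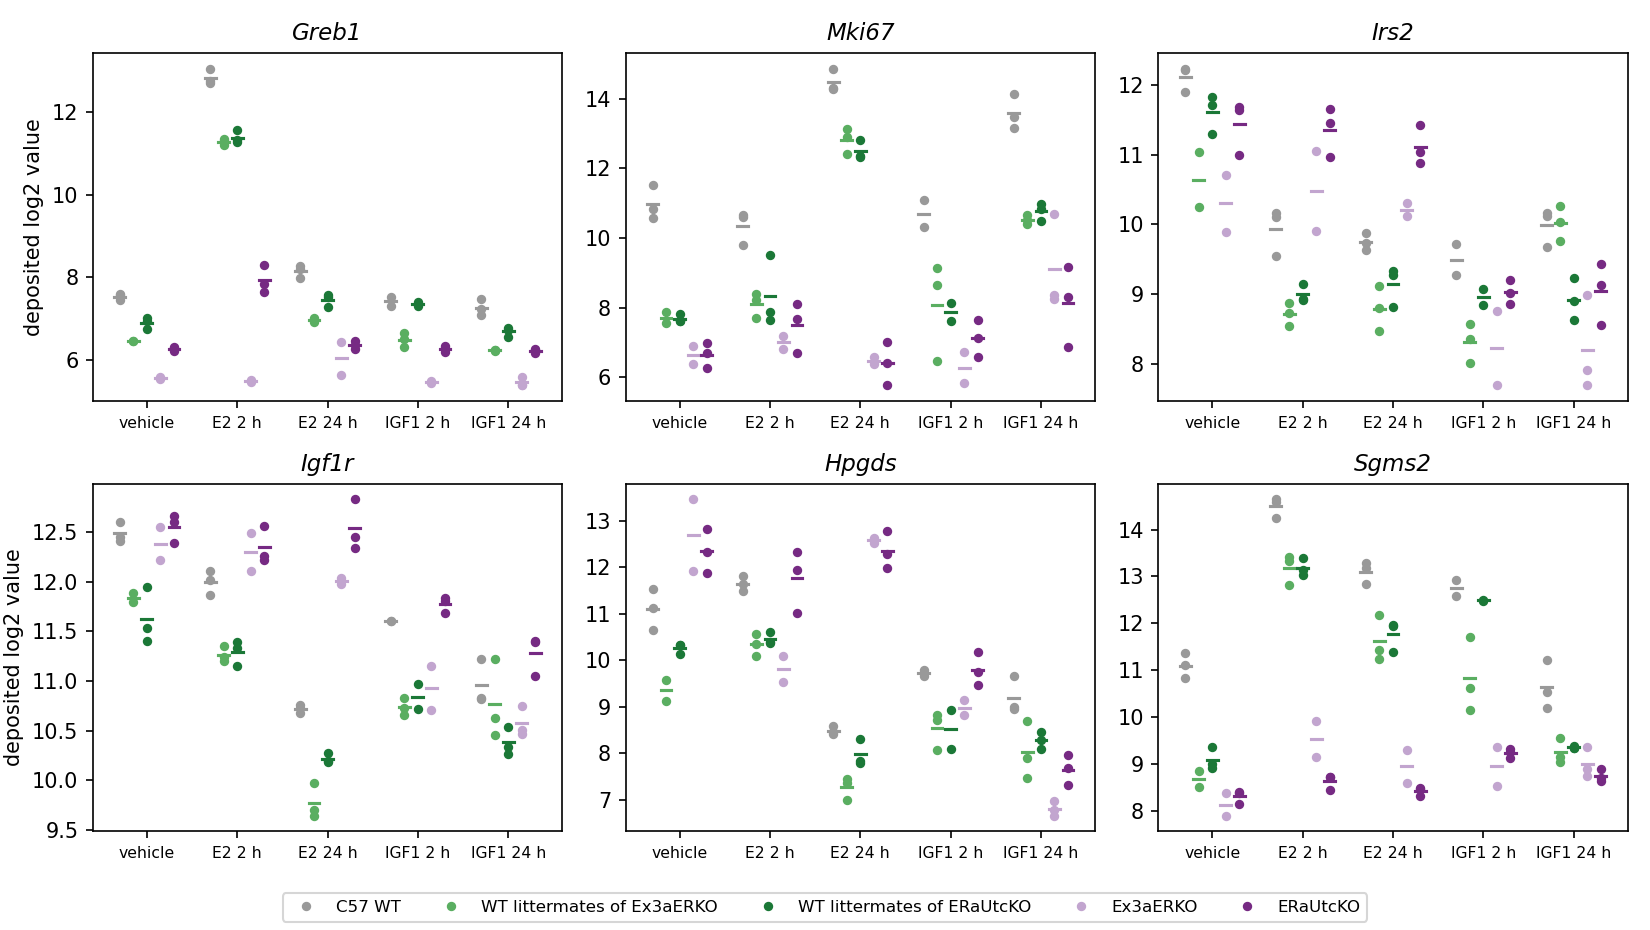
Log2 intensity of Greb1, Mki67, Irs2, Igf1r, Hpgds and Sgms2 on each array, by treatment and mouse group. Mki67 is higher 24 h after IGF1 in Ex3aERKO (2.47 above vehicle) and in ERaUtcKO (1.48), and 24 h after E2 it lies at -0.16 and -0.24 from vehicle in these lines.

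Signatures from the C57 wild types compare whole responses in mice that did not define them. Differences are medians over genes of knockout minus littermate. The 1685 genes of the 2 h E2 signature moved by a median of 1.32 in Ex3aERKO littermates and 0.05 in Ex3aERKO, a difference of -1.28 (adjusted p = 7.89e-11), and by 1.19 and 0.17 in the ERaUtcKO experiment (-1.04, adjusted p = 6.46e-13). The 2180 genes of the 24 h E2 signature moved by 1.51 and 0.06 (-1.40, adjusted p = 5.88e-09), and by 1.35 and 0.03 (-1.31, adjusted p = 2.24e-12).

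For IGF1, the 1278 genes of the 2 h signature moved by 1.27 in Ex3aERKO littermates and 1.11 in Ex3aERKO (difference -0.10, adjusted p = 0.318), and by 1.02 and 1.22 in the ERaUtcKO experiment (0.20, adjusted p = 0.0438, and adjusted p = 0.0578 with a replicate block and 0.0523 with each array centred). The 1099 genes of the 24 h signature moved by 0.82 and 0.99 (0.19, adjusted p = 0.192), and by 1.12 and 1.12 (0.02, adjusted p = 0.788). The rise of the 2 h IGF1 signature in ERaUtcKO ran from 0.12 to 0.27 with single arrays left out and missed the threshold in 9 of 11 cases (adjusted p from 0.00877 to 0.295). The 24 h difference in Ex3aERKO was 0.26 (adjusted p = 0.0481) without littermate IGF1 replicate 1.

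**Figure D3:**
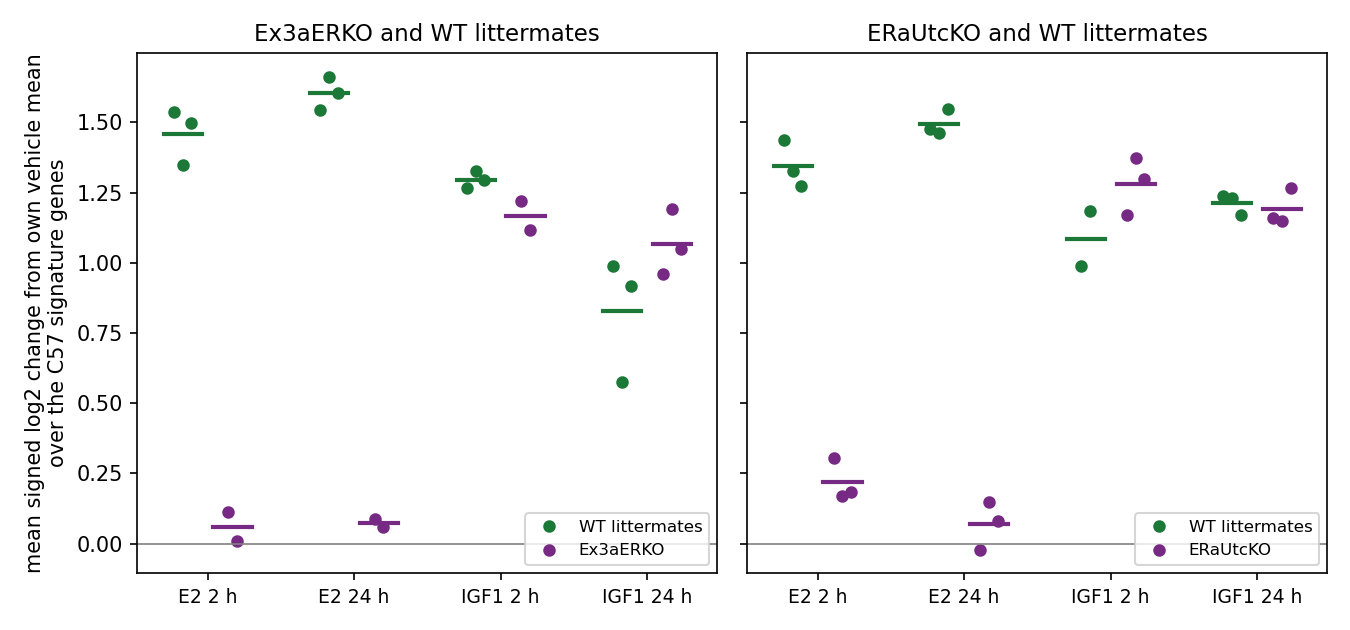
Mean signed log2 change from the vehicle mean of the same genotype, over the genes of each C57 signature, with 1 point per array, for wild-type littermates and knockouts in each line. After E2 at 24 h the knockout arrays lie between -0.02 and 0.15 and the littermate arrays between 1.46 and 1.66, and after IGF1 at 24 h knockouts lie between 0.96 and 1.27.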

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

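The tests chosen after the result was seen are the list's response to IGF1 at 2 h, the comparison of both knockout lines with its bound, the range of liver transcripts within groups and the rule for splits that keep the E2 arrays grouped, and the genes named for interactions were picked after their values were seen. The hormone responses from the early E2-responsive genes on stand out because they differed between a knockout line and its littermates by the interaction test, and liver transcripts because arrays of a group lay far apart. Glucocorticoid-responsive genes did not differ by that test at 2 h after E2 (median 0.32, adjusted p = 0.344 in Ex3aERKO and median 0.15, adjusted p = 0.888 in ERaUtcKO) and were weighed because they were raised in both knockout lines.

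Glucocorticoid-responsive genes were higher 2 h after E2 in both knockout lines, with list medians of 1.17 in Ex3aERKO and 0.91 in ERaUtcKO and 5 and 6 of 16 genes called. An effect of the injection, or of the time since it, may account for this, since vehicle tissue was taken at 24 h alone: the same list was also higher 2 h after IGF1, with the lower of both medians at 0.51 (Ex3aERKO) and the other at 0.73 (ERaUtcKO). At 24 h after E2 the medians were 0.20 and 0.05. E2 acting through another receptor cannot be told apart from this, because the lower median of E2 minus IGF1 at 2 h was 0.0720 in ERaUtcKO, with 9 of 16 genes above 0, while that of Ex3aERKO was 0.50, with 14 of 16 above 0.

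Early E2-responsive genes were partly raised 2 h after E2 in ERaUtcKO, with 7 of 20 called (3 arrays a group). In Ex3aERKO (2 a group) limma called 0 of 20 (2067 genes of all at an unadjusted p under 0.05). There Cdkn1a moved by 1.67 ± 0.61, against 1.56 ± 0.33 in ERaUtcKO. Mt2 is in the glucocorticoid list too. Separate experiments leave open injection or time, alike in both lines, as the whole cause. The median difference between the lines was 0.256, with 14 of 20 genes above 0 (camera adjusted p = 7.16e-07 over 33 lists, and adjusted p = 0.000511 with an estimated correlation), although a bound of 0.3 first set for this median was not reached and Greb1 alone was called. Cells that kept ERα in ERaUtcKO are a candidate source: the 884 signature genes that E2 moved further than IGF1 had a median response of 0.166 in ERaUtcKO and 0.0562 in Ex3aERKO (83.7% and 60% of genes in the signature's direction; fry passed 0.05 for the difference, unadjusted). At 24 h these medians were 0.0160 and 0.0935, and a difference between the experiments other than genotype stays open.

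Albumin and other liver-type transcripts differed between arrays. Liver RNA in some arrays could account for it: 17 liver transcripts from a list written before this test, none of them in another list, were all lower 24 h after IGF1 in C57 mice, with a median of -2.55, and the medians were -0.04 in Ex3aERKO littermates and -0.65 in ERaUtcKO littermates. Under vehicle in C57 the list members Apoa1 and Apoc3 stood at 7.71 and 7.15 and Alb, which is outside the list, at 16.45, levels that cannot be compared between probe sets, and 4 of the 17 lay above background in Ex3aERKO littermates. The tables argue against the hormones lowering these transcripts in the uterus as the whole cause, since within 1 group, ERaUtcKO after IGF1 at 2 h, the list median ranged over 3.42 and Alb over 6.72 log2 units (the widest of 15 groups). No biological explanation by genotype was tested for it.

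The E2 response at 2 h differed for 2841 genes in Ex3aERKO and 4154 in ERaUtcKO, and the E2 signature by -1.28 and -1.04. At 24 h it differed for 5063 and 9907 genes, and the signature by -1.40 and -1.31. As lists, early E2-responsive genes differed by -3.12 and -2.29 and immediate-early genes by -1.78 and -1.70 at 2 h. Late secretory genes differed by -2.69 and -3.02, mitosis genes by -3.05 and -3.25, cholesterol synthesis genes by -2.14 and -1.97 and epithelial markers by -2.29 and -1.73 at 24 h. With an estimated correlation these 4 lists did not pass in Ex3aERKO (adjusted p = 0.0503, 0.0629, 0.0503 and 0.0503). At 2 h in Ex3aERKO the single genes were Klk1 (-9.21), Mad2l1 (-7.34), Greb1 (-4.91), Vegfa (-4.14), Fos (-3.96), Pgr (-3.11), Igf1 (-2.59), Irs2 (2.10), Rgs2 (4.87) and Rspo3 (5.04). In ERaUtcKO they were Klk1 (-7.01), Pgf (-5.45), Fos (-3.34), Vegfa (-3.10), Greb1 (-2.83), Pgr (-1.92), Igf1 (-1.58), Irs2 (2.53), Rspo3 (3.53) and Rgs2 (3.76). At 24 h in Ex3aERKO Sprr2b differed by -7.95, Sprr1a by -6.89, Ube2c by -6.00, Mki67 by -5.25, Igf1r by 1.69, Irs2 by 1.76, Tgfbi by 4.13 and Igfbp3 by 4.2. In ERaUtcKO Sprr2f differed by -10.93, Sprr1a by -8.67, Ube2c by -6.01, Mki67 by -5.06, Ltf by -3.41, Igf1r by 1.40, Irs2 by 2.14, Igfbp3 by 3.54, Inmt by 3.92 and Tgfbi by 4.05.

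The IGF1 response at 2 h differed in ERaUtcKO for 154 genes, with its signature at 0.20, the ATF4 and amino acid list at 0.84 and the immediate-early list at 0.56. The immediate-early list did not pass with an estimated correlation (adjusted p = 0.335), and the signature did not pass in 9 of 11 runs without single arrays, with the replicate block or with centring. Single genes were Thbs1 (2.93), Egr1 (2.66), Slc7a11 (2.47), Sgms2 (-2.48), Npl (-2.39), Slc6a14 (-2.17), Adgrg7 (-2.08) and Ccl28 (-2.0). In Ex3aERKO ribosome biogenesis (-0.23), cholesterol synthesis (-0.45), unfolded protein response (-0.32) and heat-shock genes (-0.28) differed as lists at 2 h, and none passed with an estimated correlation (each adjusted p = 0.905). At 24 h it differed for 15 genes in ERaUtcKO, with the mitosis list at -1.03 and the cholesterol synthesis list at -1.05, and Hpgds (-2.71), Scpep1 (-1.42), Sqle (-1.39), Nsdhl (-1.38), Fdft1 (-1.35), Nmur1 (1.19) and Krtdap (1.29), which lay at background in 2 and 3 of 4 groups. The mitosis list did not pass there with an estimated correlation (adjusted p = 0.151). In Ex3aERKO it differed for 4 genes, Hpgds (-4.56), Coch (-2.80), Gm15765 (-1.77) and Wls (-1.70), with the mitosis list at -0.37, the interferon-stimulated list at 0.90, the cytokine list at 0.30 and the mesothelial markers at -1.20. None of these lists passed with an estimated correlation (adjusted p = 0.888, 0.132, 0.132 and 0.479), and none of their genes is among the 4.

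Other splits of the arrays were counted for comparisons with at least 3 arrays a side. In wild types treatment labels were exchanged within mouse sets. In each of the 6 comparisons 1 of 100 splits, the real one, gave as many genes, which argues against chance. The real and highest other counts were 12050 and 9416 for E2 at 2 h, 16942 and 14427 for E2 at 24 h, 10823 and 7240 for IGF1 at 2 h, and 12329 and 8112 for IGF1 at 24 h. They were 6620 and 3945 for E2 against IGF1 at 2 h and 8484 and 2615 at 24 h. Splits that exchange few labels keep much of the treatment, so the high counts of other splits are no measure of chance alone.

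Within ERaUtcKO 10 splits of 6 arrays are too few for a share under 0.05. The real and highest other counts were 1258 and 25 under vehicle, 148 and 4 for E2 at 2 h, 0 and 0 for E2 at 24 h (all 10 splits), 8824 and 103 for IGF1 at 2 h and 9765 and 0 for IGF1 at 24 h. For the interactions, genotype labels were exchanged within each treatment. As many genes were called in 10 of 100 splits for E2 at 2 h (4154, highest other 6017) and in 8 for E2 at 24 h (9907 and 11528). The signature was as far from 0 in 12 splits (1.04 and 1.14) and 12 splits (1.31 and 1.54). Each of these splits kept the E2 arrays grouped by genotype, as 12 of the 100 did by design, and so kept the difference itself, so chance cannot be told apart by this count. Among the other splits the highest counts were 65 and 17 genes and the highest signatures 0.57 and 0.66, a comparison not set beforehand. For IGF1 at 24 h as many genes as 15 were called in 18 splits (highest other 913), 10 of them with IGF1 arrays grouped. A signature as far as 0.0200 came in 74 (highest other 0.221), so chance is not excluded. The cause of the 913 was not tested.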

How the results depend on the processing

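Centring each array on its median was chosen after seeing the data, and the other alternatives before. No signature, described list or named gene passed in the opposite direction under any alternative run for it. The balance of higher and lower calls did turn over in places: with centring for both hormones at 2 h and 24 h in wild types (from 43.1% to 47.2% higher, to 56.5% to 63.4%), and in ERaUtcKO for the vehicle difference, IGF1 at 2 h and the E2 24 h interaction. Quantile normalization turned it over between both hormones at 24 h in wild types (54.3% to 46.6%), for IGF1 at 2 h there (47.1% to 50.3%), for IGF1 at 2 h and 24 h in Ex3aERKO and for the vehicle difference in ERaUtcKO, with values in the report. The filter, a 2-fold limit, single sets, only the arrays compared and single arrays left out also turned some balances over, so which direction holds more genes is not settled for these comparisons, and the cause was not tested. Apart from these balances, the filter on level, the mean of all probe sets and the signature at any fold moved no count by over 1.5 times. They moved no signature across the threshold. A further limit of 2-fold counts fewer genes by construction. In wild types it gave 1608, 2644, 1176 and 875 genes for E2 2 h, E2 24 h, IGF1 2 h and IGF1 24 h. Between both hormones it gave 761 and 569. It gave 419 and 222 genes under vehicle in Ex3aERKO and ERaUtcKO, 1600 and 1648 for IGF1 at 2 h, 1751 and 1722 for IGF1 at 24 h, and 30 for E2 at 2 h in ERaUtcKO. For the interactions it gave 1568 and 1185 for E2 at 2 h, 2799 and 3058 for E2 at 24 h, and 73 for IGF1 at 2 h in ERaUtcKO. Single mouse sets, with fewer arrays, gave 10931 (C57), 9401 (Ex3aERKO littermates) and 15980 (ERaUtcKO littermates) for E2 at 24 h, 6735 for E2 at 2 h in Ex3aERKO littermates, and 6872, 5938 and 6013 for IGF1 at 2 h. They gave 7820, 2096 and 12091 for IGF1 at 24 h (in the same order of sets), 4229, 3151 and 2803 between hormones at 2 h, and 3640, 5803 and 3173 at 24 h. With only the arrays of the groups compared, which leaves fewer degrees of freedom, the counts were 215 and 445 under vehicle, 0 and 14 for E2 at 2 h in Ex3aERKO (limma, 1701 unadjusted) and ERaUtcKO, 482 and 3230 for IGF1 at 2 h and 24 h in Ex3aERKO, 1 for the IGF1 24 h interaction in Ex3aERKO and 44 for that at 2 h in ERaUtcKO. Quantile normalization gave 16 genes for E2 at 24 h in Ex3aERKO, and the cause was not tested. A replicate block gave 9 genes for E2 at 2 h in Ex3aERKO, 4 for the IGF1 24 h interaction in ERaUtcKO and 0.20 (adjusted p = 0.0578) for the IGF1 2 h signature in ERaUtcKO, and the cause was not tested. The block gives no value for the vehicle comparison of the lines, because it holds the genotype. Centring gave 0.20 (adjusted p = 0.0523) for that signature, and the cause was not tested. With an estimated correlation 55 of 792 list tests passed instead of 271.

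With each array left out in turn, the counts ran from 165 to 770 and from 627 to 2083 under vehicle in Ex3aERKO and ERaUtcKO. For E2 at 2 h they ran from 5 to 53 and from 49 to 95, and for E2 at 24 h from 0 to 9 and from 0 to 1 (limma, against 4166 and 1151 unadjusted with all arrays). For IGF1 in Ex3aERKO they ran from 2943 to 4461 at 2 h and from 2376 to 5086 at 24 h. The interaction counts in Ex3aERKO ran from 1810 to 2705 and from 3356 to 4781 for E2 at 2 h and 24 h, from 0 to 40 for IGF1 at 2 h and from 2 to 17 for IGF1 at 24 h. In ERaUtcKO they ran from 84 to 204 for IGF1 at 2 h and from 3 to 163 for IGF1 at 24 h. The IGF1 signature ran from 0.12 to 0.27 at 2 h in ERaUtcKO (adjusted p from 0.00877 to 0.295, not passing in 9 of 11 runs) and from 0.0777 to 0.26 at 24 h in Ex3aERKO (adjusted p from 0.0481 to 0.442). A group left with 1 array is assumed to vary like the others. Of 799 values of genes named or taken from described lists, 13 lost and 3 gained their call with centring, 4 and 14 with quantile normalization, and 66 and 9 with only the arrays compared. With single arrays left out 321 of 8215 lost and 34 gained it, and with the replicate block 25 and 1 of 727. Of 117 list results described, 70 were lost with an estimated correlation, 4 with centring and 5 with quantile normalization. Signal over background limits genes such as Esr2, with a mean of 4.61 in Ex3aERKO under vehicle, where the 95th percentile of the antigenomic controls was 5.63 (5.89 in the ERaUtcKO experiment). Differences of Fos, Klk1, Sprr1a, Greb1, Cxcl15 and Gm15765 in Ex3aERKO, and of Fos, Sprr2f, Sprr1a, Adgrg7, Krtdap and Nmur1 in ERaUtcKO, involve a group under these levels, so their sizes are not exact.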

Other observations

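The tests chosen after the result was seen are those of genes with a smaller IGF1 response, the values of littermates and of vehicle differences, the fit of both lines together, and the adjustment of fry over the 14 tests of this kind. Vehicle differences were shared by both knockout lines. Of the 891 genes that differed in Ex3aERKO, 805 lay in the same direction in ERaUtcKO, with a median of 0.407, and of the 1258 from ERaUtcKO, 1064 did so in Ex3aERKO, with a median of 0.466. In a model of both lines (54 arrays), the IGF1 response differed from that of the littermates for 148 genes at 2 h (95 higher and 53 lower) and 280 at 24 h (104 higher and 176 lower), and that to E2 for 6269 and 12734. At 2 h Sgms2 differed by -1.91 ± 0.30 and Thbs1 by 2.26 ± 0.36. At 24 h Hpgds differed by -3.64 ± 0.34, Coch by -2.19 ± 0.29 and Slc6a2, the noradrenaline transporter gene, by 2.04 ± 0.31. The lines differed from each other in 1 gene for E2 at 2 h and in 0 genes in limma for the other treatments.

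A hypothesis was that a part of the IGF1 response needs ERα. Genes that responded less in ERaUtcKO than in its littermates were read in the Ex3aERKO experiment. The 32 at 2 h had a median signed difference of 0.246, with 24 in the same direction (adjusted p = 0.262), and the 10 at 24 h one of 0.222, with 7 in the same direction (adjusted p = 0.28), so neither passed and the hypothesis stays open. The first test, over all 154 and 15 genes that differed in ERaUtcKO, gave medians of 0.286 and 0.514 with 117 and 12 in the same direction (adjusted p = 0.00303 and 0.00163). It shows that the lines shared differences, and the 122 and 5 other genes passed alone (medians 0.293 and 0.622, adjusted p = 0.000609 and 0.00102), but not a need for ERα.

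A second hypothesis was that IGF1 moves genes changed by loss of ERα back towards the wild-type level. Genes that differed under vehicle in Ex3aERKO had a median signed IGF1 response at 24 h of -0.0896 in ERaUtcKO (adjusted p = 0.0703), and genes from ERaUtcKO one of -0.217 in Ex3aERKO (adjusted p = 8.31e-05). The first passed the limit of 0.05 written for it only without adjustment. The other may be in line with the hypothesis, with 409 of 1258 genes on the side of the vehicle difference. In wild-type littermates the same genes gave -0.0540 (adjusted p = 0.771) and -0.0154 (adjusted p = 0.771) after IGF1, and -0.0419 (adjusted p = 0.917) and -0.160 (adjusted p = 0.00127) after E2. Whether the IGF1 values differ between knockouts and littermates was not tested for these genes.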
